A study of Brassica rapa subsp. pekinensis with 9 samples.

How the data were processed

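RNA was extracted with a plant RNA kit for tissue rich in polysaccharides and polyphenolics, and directional libraries were prepared with the NEBNext Ultra kit, per the labels' protocols. CASAVA 1.7, cutadapt 1.15 and HISAT2 2.0.5 are listed in the submitters' processing notes, without their roles. The counting tool, the genome build, the annotation and the handling of reads shared between gene copies are not given in the sources used here. The authors deposited one table with an FPKM value for each of 47249 genes in each of the 9 libraries, and replicates were not pooled. The unit was read from the values: the columns hold decimals, sum to between 718995 and 766436, and move in steps that depend on the gene and on the library. RPKM and FPKM cannot be told apart from the values. Columns were matched to samples through the column name that each sample's description gives, and 0 further columns with values were present.

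The FPKM values carry the depth. A value is the number of reads divided by the gene's length and the library's total, so the relative depth of the libraries follows from genes with few reads, and the lengths and totals follow because both are whole numbers. Whole reads, within a tolerance of 0.0002 reads (1e-07 of the count where that is more), were found for 37664 of the 37665 genes above 0. The recovered totals lay between 13663695 and 19389805 reads, and the recovered reads of the genes in the table summed to 99.93% to 99.95% of them. Among candidate totals the one nearest to the sum of the gene reads was taken, so this closeness is no separate check of the totals. On simulated FPKM values of 36955 genes the procedure returned the exact reads for 99.75% of the genes and every library total without error. The simulated totals were set close to the sum of the gene reads, so the simulation does not test that choice. A length that shares a factor with all read counts of a gene would come out too short, which is most likely for genes with few reads. The recovered reads served for library totals, the comparison of replicates and alternatives only, since the deposited unit is FPKM. A count of 0 in a library allows up to 3 reads, and such limits cover counting error only.

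Comparisons were made on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on the group, trended prior variance, robust empirical Bayes, two-sided), with Benjamini-Hochberg adjustment over the 29630 genes at or above 0.5 FPKM in at least 3 libraries and a threshold of 0.05 on the adjusted p. All 3 groups entered one fit and shared one estimate of the spread. The design fixed before the data were examined had a count model for read counts and limma for normalized values, and the latter applied. It also had 9 separate libraries. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM. The labels call the replicates biological without saying whether they came from separate plants, so p-values measure the spread between these samples, which may be technical. Because 3 DAI replicates 1 and 2 differed, at every read count up to 3000 reads, by less than the low-count genes of the other pairs, they entered as their mean and the fit held 8 samples, and the fit with 9 separate libraries is reported beside it. The chi-square per degree of freedom compares the recovered reads of 2 libraries over genes with at least 20 reads in both together, given their totals, and its Poisson expectation is 1.

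Genes named in the text are the 2 with the highest and the 2 with the lowest log2 change in each comparison, the rule set for identifiers without names. A larger rule for named genes, the pathway lists (among them salicylic acid, jasmonate, ethylene, auxin and cytokinin genes, cell wall, cell cycle, lignin, glucosinolate, sugar, immunity and resistance genes) and the marker lists for green tissue, root hair, endodermis, xylem, phloem and cambium were fixed beforehand but could not be applied, since 0 of the 47249 identifiers matched the reference table of 51589 genes (assembly CAAS_Brap_v3.01). No coordinates of that table were used. On simulated data from the real means, lengths and totals of 29630 genes, with 200 genes changed, the fit for 3 DAI against 0 DAI recovered 2% of the genes changed 1.5-fold, 30% of those changed 2-fold, 80% of those changed 4-fold and 98% of those changed 8-fold, and 5.4% of its calls were false. For 10 DAI against 0 DAI the recovered shares were 8%, 42%, 90% and 96%, with 4.8% false calls, and for 10 DAI against 3 DAI they were 4%, 52%, 88% and 98%, with 7.6% false calls. So few changed genes make the adjusted threshold stricter than in the data, and these shares do not carry over to them. The simulated reads were drawn 2 at a time, which makes their counting noise larger than the Poisson expectation.

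Overlaps between comparisons that share libraries were set beside the overlap of independent lists, and correlations and covariances of log2 changes beside 100 simulations of unchanged groups. Alternatives covered the filter, the pseudocount, a fold threshold, a replicate block, fits of 2 groups, leaving out each library and the planned 9 separate libraries. Counting the alike pair as 1 sample was itself chosen after seeing the data, as were the alternatives of 3 DAI without the alike pair, median-of-ratios scaling, limma-voom on recovered reads and removal of a gene length trend with a spline of 4 degrees of freedom. Figures were drawn with matplotlib 3.10.9.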

Results

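RNA was sequenced from the stems and roots of Chinese cabbage (Brassica rapa subsp. pekinensis) of the genotype JQX3 inoculated with Plasmodiophora brassicae, the soil-borne protist that causes clubroot, a disease in which galls form on the roots. The 9 libraries fell into 3 groups of 3 labelled biological replicates, taken at 0, 3 and 10 days after inoculation (DAI), with 0 DAI as the control. The table gave one FPKM value (reads scaled to the length of the gene and to the reads of the library) per gene and library for 47249 genes, of which 37665 were above 0 in at least 1 library and 29630 passed the filter of 0.5 FPKM in at least 3 libraries. The library totals worked out from the steps between low FPKM values were 17722825, 19389805 and 17636878 reads at 0 DAI, 15741135, 13663695 and 17241910 at 3 DAI and 18089086, 16839111 and 19054940 at 10 DAI. Between 32558 and 33553 genes were above 0 in a library, and the 10 most abundant genes took 2.05% to 2.67% of the reads. No mock-inoculated plants of 3 or 10 DAI were analysed here, so each comparison covers inoculation together with the age of the plants and the time of sampling.

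The genes are given by identifiers of the form BraA03g059080.3.5C. The table does not pair them with gene names, and 0 of the 47249 identifiers matched the reference gene table used here. Gene functions, chromosomal coordinates and lists of pathway or tissue markers were therefore not analysed here, and genes are described by their level, their time course and the order of their identifiers. Whether the ratio of stem to root tissue differed between the libraries was not tested for the same reason.

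The replicates were compared within each group before any test. Replicates 1 and 2 at 3 DAI were far more alike than any other pair. Over genes with at least 20 reads in the pair, the chi-square per degree of freedom of their read counts was 1.98, against 12.37 to 20.93 in the other 8 pairs. It stayed at 1.92 for genes with 20 to 100 reads and at 1.98 for genes with 1000 to 3000 reads, whereas the other pairs rose from between 2.96 and 4.48 to between 12.87 and 22.07. Among genes with 5 to 20 reads, where counting noise weighs most, the alike pair had 1.86 and the other pairs 2.10 to 2.46. Up to 3000 reads the 2 libraries thus differed by less than the low-count genes of the other pairs. Their difference was above the Poisson expectation of 1, as was that of the other pairs even at 5 to 20 reads. In the alike pair 15.8% of genes had an unadjusted chi-square p under 0.05, against 36.5% to 46.8% in the other pairs. They were counted as 1 sample through their mean, a choice made after these values were seen, which leaves n = 3 at 0 DAI, n = 2 at 3 DAI and n = 3 at 10 DAI. Counts with all 9 libraries taken as separate samples are given beside the main ones.

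**Figure D1:**
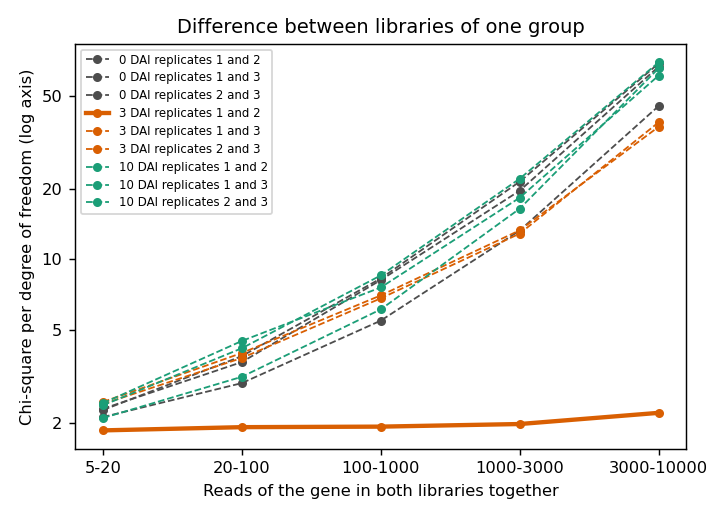
Chi-square per degree of freedom (log axis) between the read counts of 2 libraries of one group, by the number of reads of the gene in both libraries together; each line is one of the 9 pairs, and colours mark the group. The solid line, 3 DAI replicates 1 and 2, stays between 1.86 and 2.21, while the 8 dashed lines rise to between 36.76 and 69.26 for genes with 3000 to 10000 reads.

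The 3 times separated fully. The first principal component of log2(FPKM + 1) held 53.3% of the variance and placed the 3 DAI libraries at 68.4 to 72.5, the 0 DAI libraries at -15 to -9.3 and the 10 DAI libraries at -66.3 to -49.3. The second component held 23.8% and placed the 0 DAI libraries, at 35.1 to 58.3, above all others, which lay at -40.1 to -0.4. In a joint test of the 3 times, 12323 genes (41.6% of those tested) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 15130 did so with 9 separate libraries. Without 3 DAI replicate 3 the count was 7565, and the alike pair then stands alone for 3 DAI and is assumed to vary like the other groups.

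**Figure D2:**
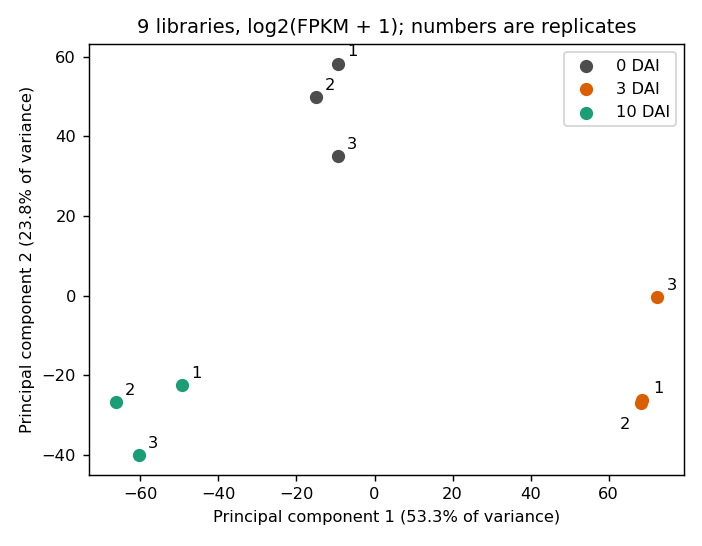
Principal components 1 (53.3% of the variance) and 2 (23.8%) of log2(FPKM + 1) over 29630 genes; each point is a library, coloured by days after inoculation and numbered by replicate. The 3 groups do not overlap, and 3 DAI replicates 1 and 2 nearly coincide, at 68.6 and 68.4 on the first component.

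The comparison of 3 DAI with 0 DAI covers the first days after inoculation. At 3 DAI, 3767 genes were higher and 3503 lower than at 0 DAI, together 24.5% of the 29630 tested. The decreases were the larger ones. Of the genes whose log2 change was at least 1, 776 rose and 1572 fell, and the median log2 change was 0.67 among genes that rose and -0.93 among genes that fell. Of the 100 most abundant genes, 21 rose and 22 fell. A set of 8 genes went from at least 5 FPKM in every 0 DAI library to under 0.5 in every 3 DAI library, and 0 did the reverse.

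On the log2(FPKM + 1) scale the highest increases at 3 DAI were those of BraA03g059080.3.5C and BraA03g059050.3.5C, whose identifiers lie close together in the numbering. BraA03g059080.3.5C rose from 1.11 ± 0.491 FPKM (SD, n = 3) to 35 ± 33.2 FPKM (SD, n = 2), a log2 change of 3.71 with a standard error of 0.61 (limma adjusted p = 0.00547). It was back at 1.40 ± 1.00 FPKM (SD, n = 3) at 10 DAI. BraA03g059050.3.5C rose from 4.59 ± 2.64 to 76.3 ± 62.4 FPKM, a log2 change of 3.60 with a standard error of 0.57 (limma adjusted p = 0.00505). In both genes the alike pair was higher than replicate 3, at 58.2 and 58.8 against 11.5 FPKM in BraA03g059080.3.5C and at 115 and 126 against 32.2 FPKM in BraA03g059050.3.5C. The deepest decreases on that scale were those of BraA04g002530.3.5C, from 454 ± 168 to 17.9 ± 14.3 FPKM (log2 change -4.76, standard error 0.60, limma adjusted p = 0.00233), and of BraA09g060510.3.5C, from 158 ± 60.2 to 5.31 ± 3.12 FPKM (log2 change -4.67, standard error 0.39, limma adjusted p = 0.000803). Without 3 DAI replicate 3 the log2 changes of BraA03g059080.3.5C, BraA03g059050.3.5C and BraA04g002530.3.5C were 4.84, 4.54 and -5.62, and with it as the only library of its group they were 2.59, 2.67 and -3.90. The order of genes depends on the pseudocount, since at 0.1 in place of 1 the 2 increases ranked 5 and 9 and the 2 decreases 19 and 18.

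Tests were two-sided moderated tests in limma on log2(FPKM + 1), and with 9 separate libraries 10270 genes were called. The count moved with the libraries that entered, as it was 4645 without 0 DAI replicate 1 and 4661 without 0 DAI replicate 2. In these fits 0 of the 7270 called genes changed direction. Fewer genes were also called in the fits that leave 1 sample at 3 DAI. Leaving out a library also removes a sample, so these falls do not show that a single library carries the result. Short genes lay higher at 3 DAI than long ones, with a median log2 change of 0.14 in the shortest of 5 length groups (median length 510 bases) and -0.07 in the longest (3112 bases). With median-of-ratios scaling of the libraries the calls were 3350 higher and 3737 lower, so which direction held more genes depends on the scaling.

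**Figure D3:**
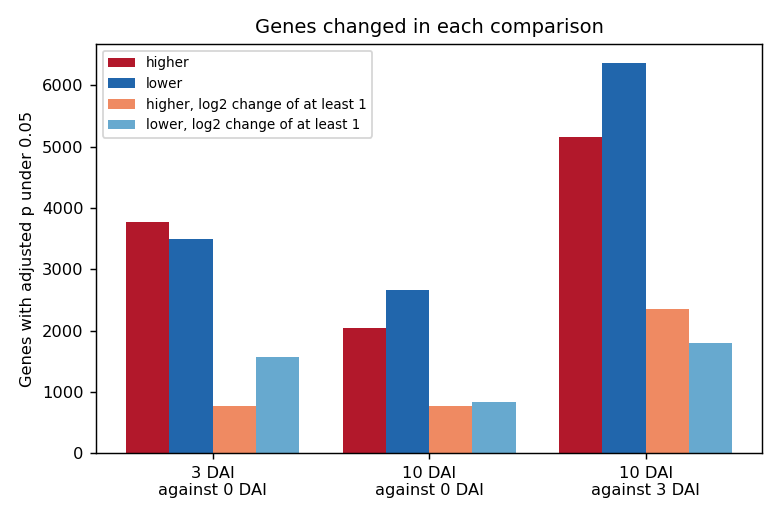
Number of genes with an adjusted p under 0.05 in each comparison, higher and lower in the later group, for all calls (dark bars) and for those with a log2 change of at least 1 (light bars). Among the larger changes, decreases outnumber increases at 3 DAI against 0 DAI (1572 and 776), and increases outnumber decreases at 10 DAI against 3 DAI (2357 and 1801).

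The comparison of 10 DAI with 0 DAI covers the whole span sampled. At 10 DAI, 2047 genes were higher and 2668 lower than at 0 DAI, 15.9% of those tested. Changes with a log2 size of at least 1 were made up of 768 increases and 831 decreases, and the median log2 change was 0.85 among genes that rose and -0.72 among genes that fell. Of the 100 most abundant genes, 4 rose and 18 fell. From under 0.5 FPKM in every 0 DAI library, 2 genes reached at least 5 FPKM in every 10 DAI library, and 5 went the opposite way.

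BraA07g039800.3.5C rose from 0.825 ± 0.899 FPKM (SD, n = 3) at 0 DAI to 255 ± 170 FPKM (SD, n = 3) at 10 DAI, a log2 change of 6.87 with a standard error of 0.65 (limma adjusted p = 0.00152). Its 10 DAI libraries held 6725, 5227 and 1150 reads and its 3 DAI libraries 1, 0 and 2, and without 10 DAI replicate 3 its log2 change was 7.70. BraA03g023410.3.5C rose from 3.25 ± 2.11 to 291 ± 108 FPKM, a log2 change of 6.14 with a standard error of 0.38 (limma adjusted p = 0.000494). BraA04g002530.3.5C, which had fallen by 3 DAI, lay at 1.83 ± 1.69 FPKM at 10 DAI, a log2 change of -7.41 against 0 DAI with a standard error of 0.54 (limma adjusted p = 0.000775). BraA07g040430.3.5C, one of the more abundant genes at 0 DAI with FPKM values of 1230, 1050 and 724, lay at 10.7 ± 4.69 FPKM at 10 DAI, a log2 change of -6.48 with a standard error of 0.86 (limma adjusted p = 0.00417). With 9 separate libraries 5557 genes were called. The count of 4715 fell to 2106 without 0 DAI replicate 1, 2589 without 0 DAI replicate 2, 2369 without 10 DAI replicate 2 and 2183 without 10 DAI replicate 3. More genes were called against 0 DAI at 3 DAI than at 10 DAI, with 7270 and 4715 genes. The order reversed without 3 DAI replicate 3 and with that replicate as the only library of its group. Both fits leave 1 sample at 3 DAI, so they cannot tell a less stable order from the loss of samples. In the alternatives with more than 1 sample at 3 DAI the order held.

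**Figure D4:**
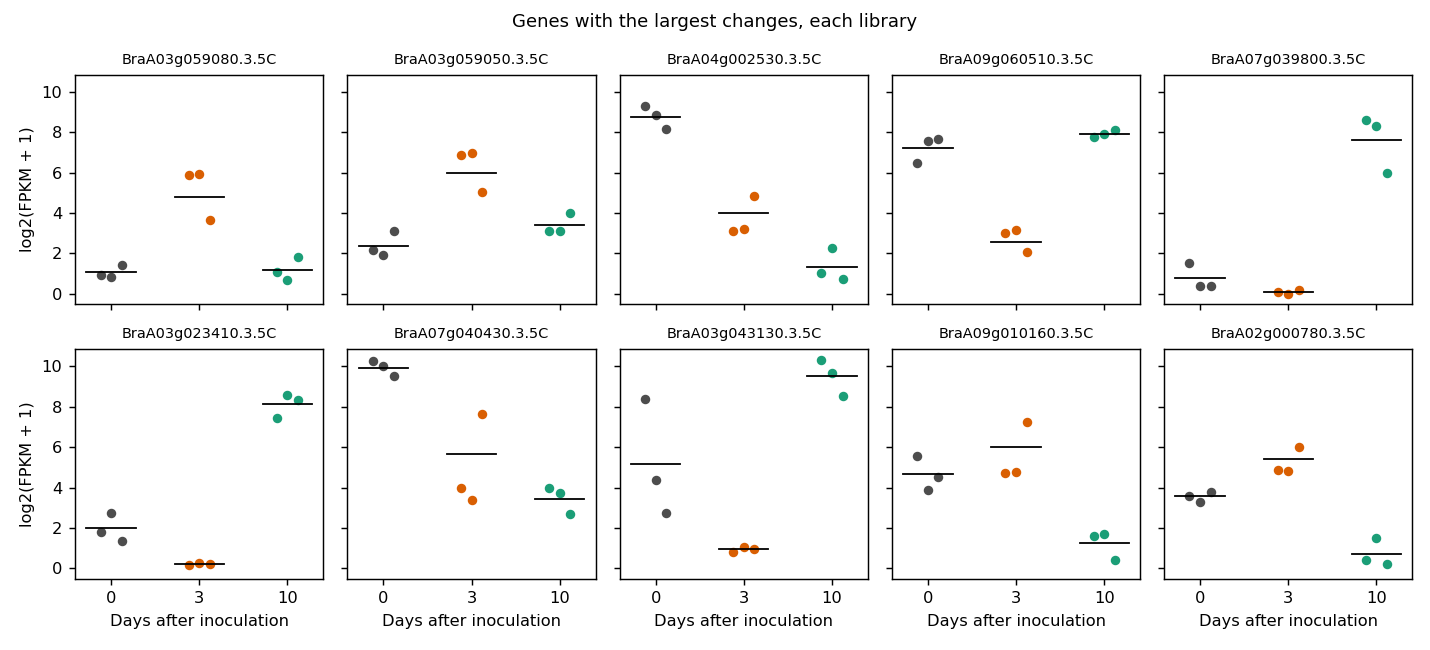
log2(FPKM + 1) of the 10 genes named in the comparisons, in each of the 9 libraries (points, replicates 1 to 3 from left to right) at 0, 3 and 10 days after inoculation; bars are group means, with 3 DAI replicates 1 and 2 averaged first. BraA04g002530.3.5C falls at each step, BraA09g060510.3.5C is low at 3 DAI alone, and BraA07g039800.3.5C and BraA03g023410.3.5C are high at 10 DAI alone.

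The comparison of 10 DAI with 3 DAI tests whether the 2 times after inoculation differed from each other, and it gave the most calls of the 3. From 3 to 10 DAI, 5168 genes rose and 6359 fell, 38.9% of those tested. Changes with a log2 size of at least 1 comprised 2357 increases and 1801 decreases, with median log2 changes of 0.93 among all genes that rose and -0.73 among all that fell. Of the 100 most abundant genes, 29 rose and 34 fell. Under 0.5 FPKM in every 3 DAI library and at least 5 FPKM in every 10 DAI library were 34 genes, against 2 genes the other way round.

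On the log2(FPKM + 1) scale the highest increases were those of BraA03g043130.3.5C and BraA03g023410.3.5C, which at a pseudocount of 0.1 ranked 3 and 2, with log2 changes of 9.44 and 10.08. BraA03g043130.3.5C went from 0.950 ± 0.0192 FPKM (SD, n = 2) at 3 DAI to 822 ± 463 FPKM (SD, n = 3) at 10 DAI, a log2 change of 8.55 with a standard error of 1.38 (limma adjusted p = 0.00251). Its 3 DAI libraries held 0.768, 1.11 and 0.964 FPKM from 8, 10 and 11 reads. The SD at 3 DAI understates that spread, since replicates 1 and 2 were averaged first. Its 0 DAI replicates spread widely, at 331, 19.4 and 5.74 FPKM, and the test on recovered reads gave an adjusted p of 0.104 (limma-voom), the highest over the alternatives, of which the lowest was 0.000424 (limma). BraA03g023410.3.5C lay at 0.158 ± 0.0108 FPKM at 3 DAI, and its log2 change to 10 DAI was 7.90 with a standard error of 0.42 (limma adjusted p = 0.000129). Its 3 DAI libraries held 0.11, 0.221 and 0.15 FPKM from 4, 7 and 6 reads, a spread that this SD understates in the same way. The deepest decreases on that scale were those of BraA09g010160.3.5C, from 87.7 ± 87.9 to 1.56 ± 1.06 FPKM (log2 change -4.73, standard error 0.76, limma adjusted p = 0.00246), and of BraA02g000780.3.5C, from 46 ± 25.6 to 0.786 ± 0.926 FPKM (log2 change -4.72, standard error 0.44, limma adjusted p = 0.000350). The 3 DAI level of BraA09g010160.3.5C was carried by replicate 3, at 150 FPKM against 25.2 and 25.9 in the alike pair, and without that library the log2 changes were -3.48 in BraA09g010160.3.5C and -4.13 in BraA02g000780.3.5C. With 9 separate libraries 13740 genes were called, and the count of 11527 fell to 6147 without 3 DAI replicate 3. With median-of-ratios scaling 5944 genes rose and 5484 fell, so here too the direction with more genes depends on the scaling.

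Most genes called at 3 DAI against 0 DAI were also called from 3 to 10 DAI in the opposite direction. Of the 3767 genes that rose by 3 DAI, 3027 fell from 3 to 10 DAI, with a median log2 change of 0.67 at the first step and -0.86 at the second. Of the 3503 genes that fell by 3 DAI, 2462 rose again, with medians of -0.98 and 1.13. Independent lists of these sizes would share 808 and 611 genes. Unchanged groups simulated on the same libraries shared 0 genes, but gave at most 3 calls in any of 100 simulations, so that this value does not measure what shared libraries add to lists of these sizes. Both comparisons use the 3 DAI libraries, so part of the excess may come from their shared deviations. Across genes, which are not independent replicates, the correlation of the 2 log2 changes was -0.72, against -0.60 in the simulation, and the covariance was -0.3262 against -0.0277, a difference of -0.2985. The 3027 genes became 1072 without 3 DAI replicate 3, 1879 without 0 DAI replicate 1 and 1877 without 0 DAI replicate 2, and the 2462 genes became 1086 without 3 DAI replicate 3.

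Fewer genes departed from 0 DAI at both later times. Higher at both were 313 genes, lower at both 654, higher at 3 DAI but lower at 10 DAI 438, and lower at 3 DAI but higher at 10 DAI 334. Independent lists would share 260, 315, 339 and 242 genes. The correlation of the 2 sets of log2 changes across genes was 0.11, against 0.45 in the simulation, and the covariance was 0.0343 against 0.0184, a difference of 0.0159. The 3 control libraries are shared and too few to split, so part of the excess may come from them in the genes higher at both and lower at both. Shared controls move both changes the same way, so this does not apply to the genes that changed in opposite directions. The value for independent lists takes all genes as equally easy to call. It therefore does not settle what the excess means in any of the 4 sets. All 4 counts moved when single libraries were left out, which also removes a sample from a small group. The genes higher at both times numbered 138 to 198 without any one of 0 DAI replicates 1 and 2, 3 DAI replicate 3 and 10 DAI replicates 2 and 3, and the genes lower at both 289 to 411 without any one of 0 DAI replicates 1 and 2 and 10 DAI replicates 2 and 3. The genes higher then lower numbered 89 to 157 without any one of the 0 DAI replicates, 3 DAI replicate 3 and 10 DAI replicates 2 and 3, and 856 without 10 DAI replicate 1. The genes lower then higher numbered 126 to 185 without any one of 0 DAI replicates 1 and 2, 3 DAI replicate 3 and 10 DAI replicates 2 and 3.

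At 10 DAI some genes differed from both earlier times. Higher at 10 DAI than at both earlier times were 1474 genes, with a median log2 change of 0.90 against 0 DAI and 1.17 against 3 DAI, and lower at 10 DAI than at both were 1512 genes, with medians of -0.64 and -0.95. These sets include the 334 genes lower then higher and the 438 genes higher then lower, which had already changed by 3 DAI. Independent lists would share 357 and 573 genes, and part of the excess may come from the 10 DAI libraries, which both comparisons use. The increases numbered 820 without 0 DAI replicate 1, 974 without 3 DAI replicate 3, 831 without 10 DAI replicate 2 and 775 without 10 DAI replicate 3. The decreases numbered 617 and 717 without 0 DAI replicates 1 and 2, 766 without 3 DAI replicate 3, and 549 and 551 without 10 DAI replicates 2 and 3.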

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

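The tests of the alike pair, of library scaling and of gene length were chosen after the result was seen. The counts of other splits and the test of depth were set beforehand.

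The effect against 0 DAI differed between 3 and 10 DAI for 438 genes that were higher at 3 DAI and lower at 10 DAI. It also did so for 334 genes that were lower at 3 DAI and higher at 10 DAI (limma, adjusted p under 0.05 in all 3 comparisons). The calls at 3 DAI and at 10 DAI against 0 DAI alone gave the same 438 and 334 genes. Opposite changes from one control imply a difference between the later times, so the test of 10 DAI against 3 DAI adds no separate support. Both sets moved when single libraries were left out, which also removes a sample. The first held 89 to 157 genes without any one of the 0 DAI replicates and 10 DAI replicates 2 and 3. It held 856 without 10 DAI replicate 1. The second held 139 to 185 without any one of 0 DAI replicates 1 and 2 and 10 DAI replicates 2 and 3. The effect also differed for 9 of the 10 named genes, a count that the naming rule favours. BraA03g043130.3.5C, BraA03g023410.3.5C, BraA09g010160.3.5C and BraA02g000780.3.5C were named for their change in this same comparison, so it is no separate test of them. The genes named at 3 DAI share the 3 DAI libraries with it. From 3 to 10 DAI the log2 change was -3.59 in BraA03g059080.3.5C, -2.58 in BraA03g059050.3.5C, -2.65 in BraA04g002530.3.5C, -4.73 in BraA09g010160.3.5C and -4.72 in BraA02g000780.3.5C. It was 5.36 in BraA09g060510.3.5C, 7.90 in BraA03g023410.3.5C and 8.55 in BraA03g043130.3.5C. In BraA07g039800.3.5C the fitted value was 7.53. The fitted values of genes with few reads at 3 DAI depend on the pseudocount, among them BraA07g039800.3.5C with 1, 0 and 2 reads, BraA03g023410.3.5C with 4, 7 and 6 reads and BraA03g043130.3.5C with 8, 10 and 11 reads. At a pseudocount of 0.1 the value was 10.08 in BraA03g023410.3.5C and 9.44 in BraA03g043130.3.5C, and it was 10.69 in BraA03g023410.3.5C under limma-voom.

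The first pattern is the likeness of 3 DAI replicates 1 and 2. From genes with 20 to 100 reads to genes with 1000 to 3000 reads, their chi-square per degree of freedom grew by a factor of 1.03, whereas the other 8 pairs grew by factors of 3.34 to 5.55. This argues against 2 separate samples that vary like the other pairs, and is consistent with one RNA sample or library deposited as 2 samples. The level near 1.9 in the alike pair is above the Poisson expectation of 1. Among genes with 5 to 20 reads the other pairs were above 1 too, at 2.10 to 2.46. A level above 1 is thus not particular to the alike pair, and its cause was not tested. Which label is affected stays open, and no biological explanation was tested.

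The second pattern is the reversal of 5489 genes, called at 3 DAI against 0 DAI and called in the opposite direction from 3 to 10 DAI. A return to the 0 DAI level was not required. The set includes the 438 genes higher then lower and the 334 genes lower then higher, which passed beyond that level. Lower depth at 3 DAI is argued against, since 5202 genes showed the pattern with all libraries thinned to the smallest sum of gene reads, 13656783. Library scaling and the gene length trend are argued against in the same way, with 5339 genes under median-of-ratios scaling and 5285 with the length trend removed. The share of stem and root tissue and any difference in library handling between the groups were not tested. These, a response to inoculation, the age of the plants and the hour of sampling stay open for the pattern, as the groups confound them. It may also rest in part on the few samples at 3 DAI, since without 3 DAI replicate 3 the 2 directions held 1072 and 1086 genes, and the genes that rose and fell again numbered 1879 and 1877 without 0 DAI replicates 1 and 2.

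In the joint test of the 3 times, 1 of 100 splits drawn from the 280 possible, the real one, reached 12323 genes. The highest other split gave 3945. This argues against chance at a share of 1 in 100, with the samples taken as independent. Each pairwise comparison allows 10 splits, too few for a share under 0.05, and the real one was the only 1 of the 10 to reach its count. The real counts were 7270 genes at 3 DAI against 0 DAI, 4715 at 10 DAI against 0 DAI and 11527 at 10 DAI against 3 DAI, and the highest of the other splits gave 0, 0 and 2 genes.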

How the results depend on the processing

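The fit with 9 separate libraries was the planned one, and counting the alike pair as 1 sample was chosen after seeing the data. The alternatives with 3 DAI replicate 3 as the only library of its group, median-of-ratios scaling, limma-voom and the length trend were also chosen then. The 4 counts of changed genes stayed within 1.5 times of the main value with no filter, a stricter filter of 1 FPKM, a pseudocount of 0.1, fits of 2 groups, 9 separate libraries, median-of-ratios scaling, limma-voom on recovered reads and removal of the length trend (fits of 2 groups give 3 of the 4 counts). With a log2 change of at least 1 required, 2348, 1599 and 4158 genes were called at 3 DAI against 0 DAI, 10 DAI against 0 DAI and 10 DAI against 3 DAI, which follows from the added criterion. With 3 DAI replicate 3 as the only library of its group, 2845 genes were called at 3 DAI against 0 DAI and 8184 over the 3 times. Leaving out single libraries gave 3074 to 7342 genes at 3 DAI against 0 DAI, 2106 to 5142 at 10 DAI against 0 DAI, 6147 to 11660 at 10 DAI against 3 DAI and 7565 to 12387 over the 3 times. Genes higher at both 3 and 10 DAI than at 0 DAI numbered 138 to 340 when single libraries were left out, those lower at both 289 to 700, those higher then lower 89 to 856, and those lower then higher 126 to 407. Genes that rose by 3 DAI and fell again numbered 1072 to 3083, those that fell and rose again 1086 to 2465, those higher at 10 DAI than at both other times 775 to 1547, and those lower 549 to 2015. The first 6 of these overlaps were 92, 277, 165, 150, 1184 and 1186 with 3 DAI replicate 3 alone. With 9 separate libraries the first 4 were 481, 1016, 712 and 522. Genes higher then lower numbered 290 with no filter and 268 in fits of 2 groups. The cause of these moves was not tested. Whether replicate numbers pair the samples was not settled. Of 9 same-numbered pairs, 2 had a correlation of deviations over 0.1 (range -0.19 to 0.30). Pairs with 3 DAI tell little, since replicates 1 and 2 there were alike. Between 0 and 10 DAI the same-numbered pairs had 0.02, 0.30 and 0.24, and differently numbered pairs -0.29 to 0.05. A replicate block over 9 separate libraries gave 9850, 5067, 13415 and 14517 genes and 561 genes lower then higher, and moved no other count by over 1.5 times against the main values. The named genes were picked for the largest changes in these same data, which favours calls that hold under the alternatives. Of 228 values of the named genes under the alternatives, 227 kept their direction and call and 0 reversed. The exception was BraA03g043130.3.5C from 3 to 10 DAI under limma-voom (log2 change 9.55, adjusted p 0.104; over all its alternatives 0.000424 to 0.104). Median-of-ratios scaling moved the share of higher calls from 51.8% to 47.3%, 43.4% to 47.8% and 44.8% to 52.0% in the 3 comparisons. Alternatives planned for count tables were not run because the table holds FPKM, and the gene list alternatives because no identifier could be named. How far depth limits the calls was tested only by thinning all libraries to the smallest sum of gene reads, 13656783. This gave 5202 genes called at 3 DAI against 0 DAI and in the opposite direction from 3 to 10 DAI, against 5489 in full.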

Other observations

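The test of chance placement was chosen after the pattern was seen, and the test of shared reads was set before its result.

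Genes with neighbouring identifiers tended to be called in the same direction. At 3 DAI against 0 DAI, 763 of 20633 adjacent pairs were both higher or both lower, against a mean of 633 and a highest of 718 in 1000 permutations of the calls among genes of similar level, which argues against chance placement. Among changes with a log2 size of at least 1, the ratio of observed to mean permuted pairs was 1.73 at 3 DAI (126 pairs against 73) and 2.43 at 10 DAI (73 pairs against 30), each against 0 DAI, and 1.69 from 3 to 10 DAI (352 pairs against 209). Over all calls the ratios were 1.21, 1.32 and 1.21. BraA03g059050.3.5C and BraA03g059080.3.5C, the highest increases at 3 DAI on the log2(FPKM + 1) scale, lie near each other but do not form one unbroken stretch. Another gene with a log2 change of 3.47 follows directly after BraA03g059080.3.5C, and one between the pair fell by 1.90 on the log2 scale (limma adjusted p = 0.0181 and 0.0229; both chosen after their values were seen). The longest stretches of such changes in one direction held 5 genes, with a median log2 change of 1.93 at 10 DAI against 0 DAI and 2.20 from 3 to 10 DAI.

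A candidate explanation is reads shared by near-identical neighbouring copies. Among pairs whose recovered lengths differ by more than 25%, 533 were called the same way at 3 DAI against a highest permuted value of 530, and 1389 against 1277 from 3 to 10 DAI, but at 10 DAI against 0 DAI the 235 pairs stayed under the highest permuted value of 251. Among changes with a log2 size of at least 1, such pairs exceeded the highest permuted value in each comparison (84 against 77 at 3 DAI and 45 against 37 at 10 DAI, each against 0 DAI, and 239 against 193 from 3 to 10 DAI). Copies of different annotated length can also share reads, so shared reads and local co-regulation of tandem genes cannot be told apart without the gene sequences. That adjacent identifiers lie next to each other on a chromosome was assumed from their numbering and not tested.

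The trend with gene length followed the 3 DAI libraries. The median deviation of the shortest of 5 length groups minus that of the longest, on the log2 scale against the mean of all libraries, was 0.124, 0.134 and 0.207 in the 3 DAI libraries, -0.116, -0.076 and 0.021 at 0 DAI and -0.108, -0.122 and -0.109 at 10 DAI. Spearman's rho of log2 change with length across genes was -0.15 at 3 DAI and 0.05 at 10 DAI, each against 0 DAI.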
